A study of Mus musculus with 11 samples.

How the data were processed

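RNA was measured in 11 libraries of a mouse acinar cell line in 4 groups, of 2 (control siRNA), 3 (control siRNA with EGF), 3 (Arid1a siRNAs) and 3 (Arid1a siRNAs with EGF). Polyadenylated RNA was prepared with a TruSeq RNA v2 kit, which does not mark the strand, so reads of a gene cannot be told from reads of a transcript on the other strand. Per the submitters' processing notes, the authors aligned reads with TopHat2 2.1.1 to the mouse build mm9 and counted them with HTSeq 0.9.1. They further name Cuffnorm 2.2.1.2 and Cuffdiff 2.2.1.5. The deposited tables for each library hold raw read counts per gene symbol, with no further normalisation. The annotation and the counting settings are not stated. A deposited table of the series holds FPKM values from Cuffnorm, normalised by the authors in a way that is not stated. Its 3 control columns could not be matched to the 2 control libraries and were not used, and the other 9 columns served as an alternative. No coordinates are given, because the reference at hand is of another build. Of the symbols, 20882 (89.7%) are gene names in GENCODE vM21.

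The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13343 genes (57.3%) with 99.96% of the reads. Libraries were scaled with TMM factors, and a model with 4 group means over all 11 libraries was fitted by the quasi-likelihood method with robust estimates (7 residual and 7.45 prior degrees of freedom, common dispersion 0.00490, biological coefficient of variation 7.00%). The 5 comparisons were EGF with control siRNA, Arid1a siRNAs without EGF, Arid1a siRNAs with EGF, EGF with Arid1a siRNAs, and the difference between the EGF responses (interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no minimum fold. Counted reads per library were 19773007 and 14059719 for control siRNA replicates 1 and 2, and 14292775, 16796787 and 13547278 for those with EGF. The libraries with Arid1a siRNAs held 10279763, 15710575 and 11199245 reads, and those with Arid1a siRNAs and EGF 14143225, 13614553 and 11947581.

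Before the data were examined, 27 gene lists with 724 distinct genes were written, of which 603 were tested and 9 stand in more than 1 list. They cover acinar enzymes, acinar transcription factors, ductal and metaplasia markers, progenitor and Notch genes, ERK targets, immediate early genes, the EGF receptor family, NFAT genes, SWI/SNF subunits, EMT genes, integrins and proteases, YAP, TGF-beta, Wnt and SREBP targets, cell cycle genes, p53, interferon, NF-kB, unfolded protein and amino acid responses, glycolysis, and markers of islet, fibroblast, immune and endothelial cells. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested members), adjusted over the lists within each comparison, and again with an estimated correlation. Genes are named by a rule of the same date: the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the libraries of the groups compared, the 3 members with the smallest p of each called list, and in each comparison Arid1a, Egfr, Nfatc1, Sox9, Krt19, Cpa1, Ptf1a, Nr5a2, Bhlha15 and Dusp6, with Arid1b, Smarca4 and Arid2 for the siRNAs. For the interaction libraries need not be apart. Clone-type symbols (Gm, Rik, LOC, BC and AI) were passed over, and some members are given only in counts. A few genes that meet the rule are not reported here. The values of Gprc5a, Spry1 and Wipi1 in further comparisons were added after they were seen, as were the immune cell markers.

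The test was checked on counts simulated from the means, depths and dispersions of the data, with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold among 13036 to 13049. It recovered 64.2%, 86.6% and 97.0% for EGF with control siRNA. The shares were 56.7%, 74.6% and 90.9% for Arid1a siRNAs without EGF, and 79.1%, 86.6% and 95.5% with EGF. They were 67.2%, 82.1% and 95.5% for EGF with Arid1a siRNAs, and 41.8%, 86.6% and 97.0% for the interaction. Between 3 and 12 unchanged genes were called per comparison. In the data 23.4% to 46.9% of genes were called in the comparisons other than the interaction, far more than were changed in the simulations. The adjusted threshold is then less strict, so the recovered shares and false calls need not carry over to those comparisons. Pairs of libraries of a group were checked for copies, and over genes with at least 20 reads their chi-square per degree of freedom was 1.57 to 10.9, where reads drawn again from 1 library would give about 1.

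Replicate numbers come from the sample labels. Over the 3 same-number pairs of control siRNA with EGF and Arid1a siRNAs with EGF, deviations from the group means correlated at 0.14, 0.30 and 0.13, against -0.19 to 0.07 for different numbers. Because deviations are centred within each group, positive same-number values push the others to be negative, so the contrast is no separate support. Between other groups, libraries of different numbers correlated at up to 0.38. The numbers may pair these libraries, but the data do not settle it. The main fit has no block.

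The alternatives were RLE and upper-quartile factors, no filter or a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, edgeR with legacy=FALSE, only the groups compared, the replicate number as a block, a minimum change of 1.5-fold (glmTreat), an adjusted p under 0.01, fry for the lists, leaving out each library, and limma on log2 FPKM (minimum mean 1 or none, pseudocount 1 or 0.1). A within-group component of log2 CPM (prior count 2) as a covariate was added later, as was the block with only the groups compared for Arid1a siRNAs with EGF. Words of 7 bases in 3′ UTRs (GENCODE vM21, at least 50 bases, 11524 genes) were related to log2 changes limited to 2 in size, with UTR length and GC content as covariates, for 15710 words found in at least 100 genes each, beside 100 permutations over genes.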

Results

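The libraries were made from a mouse pancreatic acinar cell line that still makes digestive enzymes. The series asks how EGF receptor signalling and ARID1A act together on the transcriptome of cells that can change identity. Arid1a encodes a DNA-binding subunit of the BAF form of the SWI/SNF chromatin remodelling complex. Cells received a non-targeting control siRNA or siRNAs against Arid1a (25 nM) for 48 h, were kept without serum overnight, and were then given EGF (40 ng/ml) or the 0.1% BSA vehicle for 8 h. No concentration is recorded for the control siRNA. The 11 libraries fall into 4 groups: control siRNA (n = 2), control siRNA with EGF (n = 3), Arid1a siRNAs (n = 3) and Arid1a siRNAs with EGF (n = 3). Depth was 14059719 to 19773007, 13547278 to 16796787, 10279763 to 15710575 and 11947581 to 14143225 counted reads in these groups. Enough reads to be tested were found for 13343 genes, 57.3% of those listed. No label says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes are edgeR fold changes with the log2 change ± its standard error, levels are mean CPM ± SD, and adjusted p-values are Benjamini-Hochberg values over all genes tested unless stated otherwise.

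Arid1a stood at 292 and 399.9 CPM in the libraries with control siRNA, at 308, 263 and 300.2 CPM with control siRNA and EGF, at 151, 157 and 127 CPM with Arid1a siRNAs, and at 145, 122 and 152 CPM with Arid1a siRNAs and EGF. Its RNA was 2.38-fold lower with the Arid1a siRNAs without EGF (log2 -1.25 ± 0.13, edgeR adjusted p = 2.36e-05) and 2.08-fold lower with EGF (log2 -1.06 ± 0.12, edgeR adjusted p = 2.85e-05), and each library with Arid1a siRNAs lay below each library with control siRNA. EGF itself gave Arid1a a log2 change of -0.25 ± 0.13 with control siRNA (edgeR adjusted p = 0.174), and the change was called without siCtrl replicate 1 (log2 -0.47, edgeR adjusted p = 0.0155). Arid1b, which encodes the alternative to ARID1A in the complex, Smarca4, which encodes its ATPase, and Arid2, a subunit of the related PBAF complex, had log2 changes of -0.19 ± 0.10, 0.06 ± 0.06 and 0.02 ± 0.13 with the Arid1a siRNAs without EGF. None of the 3 passed the test there or with EGF. The within-group component as a covariate, which removes spread within groups, called Arid1b lower without EGF (log2 -0.20, edgeR adjusted p = 0.000712). As the component was drawn from the same libraries, that smaller p-value is no separate support. With EGF, a fit of only the 2 groups compared with the replicate number as a block called Arid2 lower (log2 -0.08, edgeR adjusted p = 0.0345). This fit was added later and has 2 residual degrees of freedom, and the block over all libraries did not call Arid2.

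**Figure D1:**
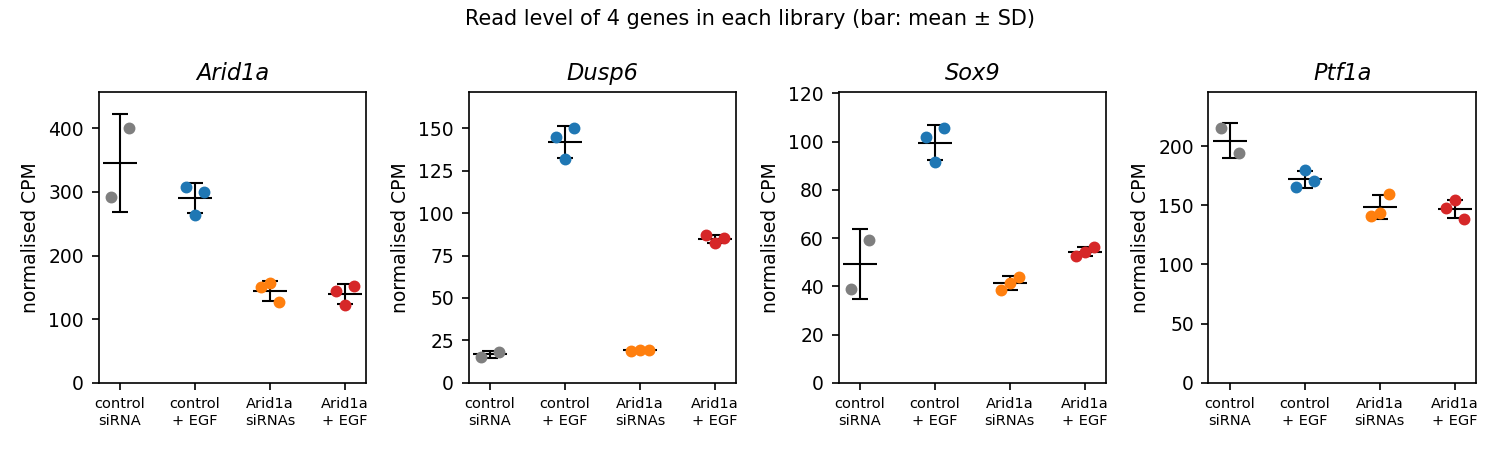
Normalised CPM (y axis, from 0) of Arid1a, Dusp6, Sox9 and Ptf1a in each of the 4 groups (x axis), 1 point per library, with the mean and SD as bars (n = 2 for control siRNA, n = 3 elsewhere). Arid1a lies between 122 and 157 CPM in the libraries with Arid1a siRNAs and between 263 and 399.9 CPM in the others, and Dusp6 rises 8.48-fold with EGF after control siRNA and 4.43-fold after Arid1a siRNAs.

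The first comparison asked what EGF changes in acinar cells with control siRNA (n = 3 against n = 2). Genes that restrain or relay ERK signalling rose most clearly. Dusp6, a phosphatase of ERK, rose 8.48-fold, from 16.8 ± 2.01 to 142 ± 9.39 CPM (log2 3.08 ± 0.09). The ETS transcription factor gene Etv4 rose 15-fold (log2 3.90 ± 0.13), and Spry4 and Spry1, inhibitors of receptor tyrosine kinase signalling, rose 12-fold (log2 3.59 ± 0.16) and 8.57-fold (log2 3.10 ± 0.11). Has2, which makes hyaluronan, the collagen gene Col15a1 and the ceramidase gene Acer2 rose 11.1-fold, 10.4-fold and 9.34-fold, and Samd5 rose 47.0-fold from 0.999 ± 0.411 CPM, a low level that leaves its fold uncertain (log2 5.55 ± 0.44). Among ERK feedback and ETS target genes, 19 of 26 rose, 1 fell and 6 did not pass. 19 higher and 1 lower passed when adjusted over the list alone (camera adjusted p = 2.49e-40, adjusted p = 0.00306 with an estimated correlation). Among immediate early and AP-1 genes, 18 of 28 rose, 5 fell and 5 did not pass. 18 higher and 5 lower passed when adjusted over the list alone (camera adjusted p = 1.17e-06, adjusted p = 0.00708 with an estimated correlation). Maff and Egr1 rose 4.91-fold (log2 2.30 ± 0.12) and 3.11-fold (log2 1.64 ± 0.08), and Myc rose 1.98-fold.

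The genes that fell most with EGF were Synpo2, an actin-binding protein gene, by 7.46-fold (log2 -2.90 ± 0.17), Pcdh8, a protocadherin gene, by 6.79-fold (log2 -2.76 ± 0.10), and the epithelial transcription factor gene Grhl3 by 4.97-fold (log2 -2.31 ± 0.12). Fam13a, Olfml2b, the adrenergic receptor gene Adra2a, Apol7a and Pcdh15 followed at 4.92-fold, 4.81-fold, 4.61-fold, 4.54-fold and 3.96-fold. Acinar identity genes went both ways. Cpa1, a carboxypeptidase, Reg1 and the lipase-related Pnliprp1 fell 1.40-fold (log2 -0.48 ± 0.07), 1.62-fold (log2 -0.69 ± 0.08) and 1.54-fold (log2 -0.62 ± 0.09), and in the list of acinar digestive enzymes and secretory products, 1 of 28 rose, 14 fell and 13 did not pass. 2 higher and 14 lower passed when adjusted over the list alone (camera adjusted p = 0.000870, adjusted p = 0.441 with an estimated correlation). Bhlha15 (Mist1), a transcription factor of secretory cells, rose 2.21-fold (log2 1.15 ± 0.15), as did Sox9, a ductal and progenitor factor, by 2.04-fold (log2 1.03 ± 0.13). Smaller changes were a rise of Nr5a2 (log2 0.42 ± 0.11) and Egfr (log2 0.61 ± 0.18) and a fall of the acinar factor gene Ptf1a (log2 -0.25 ± 0.07). These 3 calls were lost without siCtrl replicate 1, at log2 0.27, 0.36 and -0.18 with edgeR adjusted p = 0.139, 0.206 and 0.125, those of Egfr and Ptf1a also without siCtrl_EGF replicate 1 (edgeR adjusted p = 0.0590 and 0.0545), and that of Egfr with no filter on low counts (edgeR adjusted p = 0.0707). The ductal keratin gene Krt19 lay between 0.846 and 2.15 CPM in the 11 libraries and its fall (log2 -0.91 ± 0.26, edgeR adjusted p = 0.0142) was lost without siCtrl replicate 2 (edgeR adjusted p = 0.0954) and with DESeq2 (adjusted p = 0.0713). Nfatc1 had a log2 change of 0.23 ± 0.10 (edgeR adjusted p = 0.0882) and was called without siCtrl_EGF replicate 2 (0.32, edgeR adjusted p = 0.0187).

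Further lists moved with EGF after control siRNA. Of the amino acid response and ATF4 genes, 16 of 29 rose, 2 fell and 11 did not pass. 17 higher and 2 lower passed when adjusted over the list alone (camera adjusted p = 6.34e-06, adjusted p = 0.223 with an estimated correlation), including the amino acid transporter gene Slc7a5 (1.69-fold) and the serine and folate pathway genes Psat1 (1.65-fold) and Mthfd2 (1.56-fold). For cholesterol biosynthesis and SREBP2 targets, 14 of 24 rose, 0 fell and 10 did not pass. 14 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 9.33e-05, adjusted p = 0.331 with an estimated correlation), with Cyp51 up 1.34-fold. In the list of integrins, matrix and protease genes, 12 of 25 rose, 4 fell and 9 did not pass. 12 higher and 4 lower passed when adjusted over the list alone (camera adjusted p = 0.00583, adjusted p = 0.326 with an estimated correlation): the urokinase receptor gene Plaur rose 9.63-fold and Timp3 2.26-fold, and Adamts1 fell 1.72-fold. Among mesenchymal and EMT genes, 8 of 21 rose, 1 fell and 12 did not pass. 8 higher and 1 lower passed when adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.235 with an estimated correlation), with Tgfbi and Tgfb1 up 3.23-fold and 1.67-fold. Beside these 2 lists, 3 of 14 tested fibroblast and stellate markers rose and 2 fell, with a mean log2 change of 0.17 and a 95% interval from 0.0139 to 0.320 (camera adjusted p = 0.447). Of the ductal and metaplasia markers, 13 of 30 rose, 3 fell and 14 did not pass. 13 higher and 3 lower passed when adjusted over the list alone (camera adjusted p = 0.0383, adjusted p = 0.235 with an estimated correlation). Spp1 (osteopontin) and Onecut3 rose 5.55-fold and 4.50-fold, and Elf3 fell 2.01-fold. The G2/M genes were lower: 0 of 32 rose, 23 fell and 9 did not pass. 0 higher and 23 lower passed when adjusted over the list alone (camera adjusted p = 1.63e-06, adjusted p = 0.179 with an estimated correlation). The interferon response genes were lower as well: 0 of 36 rose, 19 fell and 17 did not pass. 2 higher and 21 lower passed when adjusted over the list alone (camera adjusted p = 0.000550, adjusted p = 0.331 with an estimated correlation). Nusap1 and Ccnb2 fell 1.84-fold and 1.56-fold, and Stat2 and Rtp4 fell 1.57-fold and 1.67-fold. In the list of progenitor and Notch pathway genes, 4 of 25 rose, 11 fell and 10 did not pass. 5 higher and 12 lower passed when adjusted over the list alone (camera adjusted p = 0.0388, adjusted p = 0.331 with an estimated correlation), with the Notch ligand gene Dll1 down 2.46-fold and Klf4 up 3.44-fold. For S-phase and E2F genes, 0 of 33 rose, 9 fell and 24 did not pass. 0 higher and 9 lower passed when adjusted over the list alone (camera adjusted p = 0.0456, adjusted p = 0.496 with an estimated correlation), with Tk1 and E2f2 down 1.58-fold and 1.40-fold.

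In all, edgeR's quasi-likelihood test called 4744 genes for EGF with control siRNA (2237 higher, 2507 lower), 672 of them by more than 2-fold. Left-out libraries ended list calls by camera: without siCtrl replicate 1 the enzymes, ductal markers and integrins stood at adjusted p = 0.0633 each and the EMT genes at 0.0687, and without siArid1a replicate 3 the ductal markers at 0.0517. A component of the spread within groups as a covariate also ended the camera call of the ductal markers (adjusted p = 0.0853). The progenitor and Notch genes were lost without siCtrl replicate 2 (camera adjusted p = 0.105), siCtrl_EGF replicate 2 (0.0742) or siCtrl_EGF replicate 3 (0.0656). The S-phase genes were lost in 8 of 11 such fits (highest 0.0623, without siCtrl_EGF replicate 1) and with RLE factors (0.0523). Without siCtrl replicate 2, camera also called the EGF receptor family (adjusted p = 0.0439), YAP (0.0483), Wnt (0.0216) and fatty acid synthesis (0.0323) lists.

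**Figure D2:**
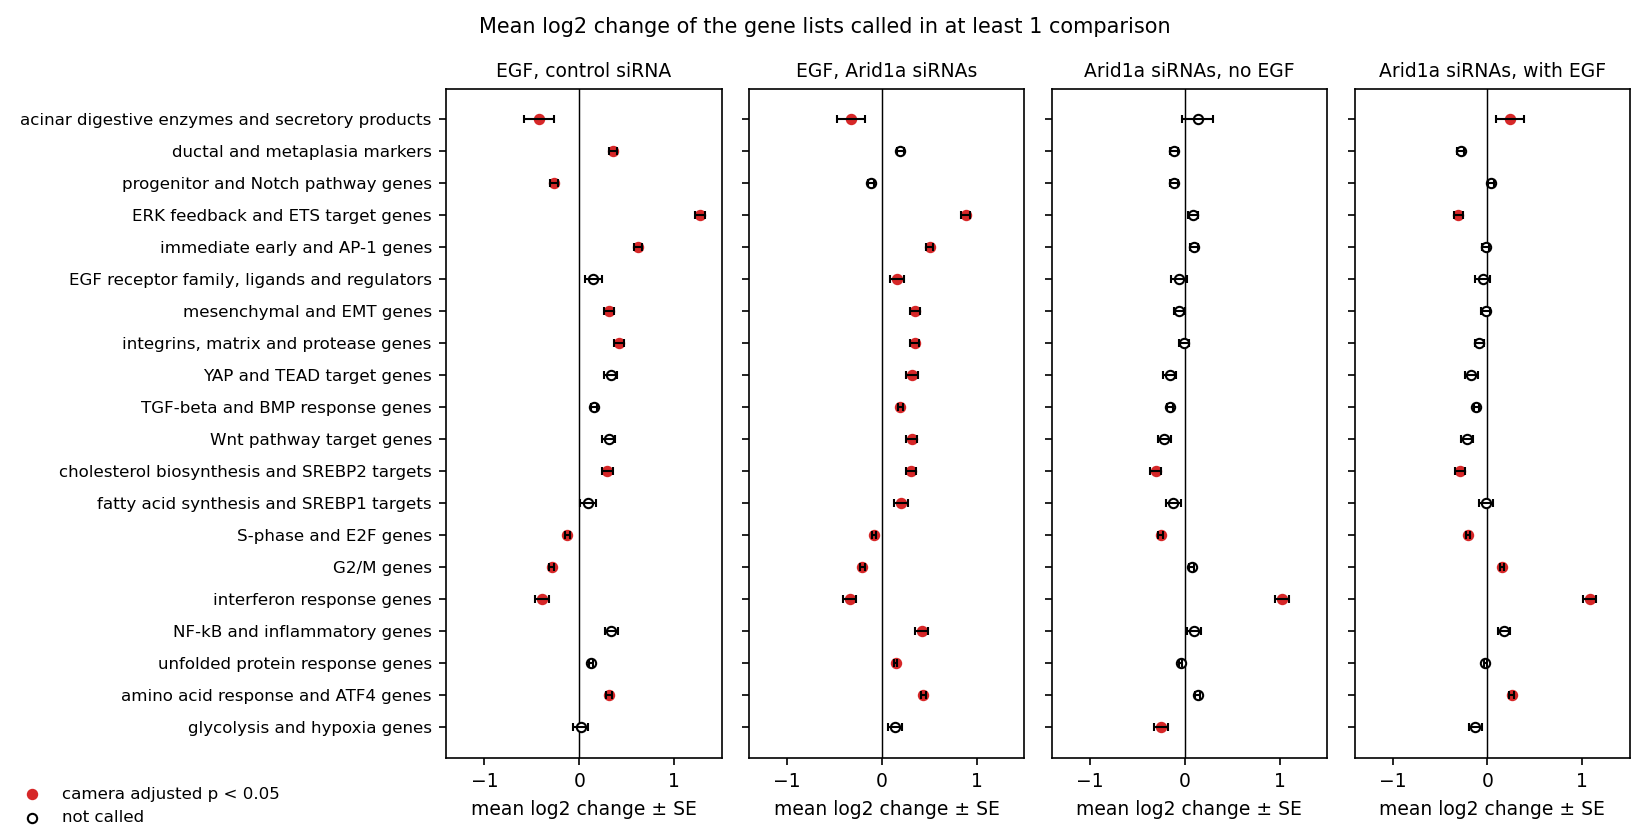
Mean log2 change of each gene list called in at least 1 comparison (x axis, log2 scale) with its standard error, for EGF with control siRNA, EGF with Arid1a siRNAs, and Arid1a siRNAs without and with EGF, where filled red points have a camera adjusted p under 0.05 and open points do not. The ERK list rises by 1.27 and 0.88 with EGF after control and Arid1a siRNAs, and the interferon list is higher by 1.03 and 1.08 with Arid1a siRNAs without and with EGF.

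The next comparison asked what lower Arid1a changes in cells without EGF (n = 3 against n = 2). Genes of the interferon response were higher together. Irf7, a master transcription factor of that response, rose 4.06-fold, from 10.9 ± 0.932 to 43.9 ± 4.26 CPM (log2 2.02 ± 0.12), Igtp and Irf9 rose 2.48-fold (log2 1.31 ± 0.10) and 2.32-fold (log2 1.22 ± 0.10), and Ifit1 rose 3.83-fold. Among interferon response genes, 30 of 36 rose, 0 fell and 6 did not pass. 30 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 6.69e-24, adjusted p = 0.105 with an estimated correlation), and the median log2 change was 1.02. The Oas, Ifit and Igtp families hold similar genes whose reads can be split between them, so single members are uncertain. Among 7 tested immune and endothelial markers, 3 rose and 1 fell in the same comparison, and their mean log2 change was 0.21 with a 95% interval from 0.0384 to 0.383 (camera adjusted p = 0.424). Of 14 tested fibroblast and stellate markers, 5 rose and 2 fell, with a mean of 0.23 and an interval from 0.0807 to 0.387 (camera adjusted p = 0.466). Outside the interferon list, Angptl4, an inhibitor of lipoprotein lipase, rose 5.59-fold (log2 2.48 ± 0.19), the ATP-gated channel gene P2rx6 4.61-fold (log2 2.2 ± 0.16), the carboxyl ester lipase gene Cel 4.40-fold (log2 2.14 ± 0.21) and Creb3l3 3.91-fold (log2 1.97 ± 0.16). The death ligand gene Tnfsf10 (TRAIL), also outside the interferon list, rose 3.51-fold. Samd5 was 3.54-fold higher (log2 1.83 ± 0.61, edgeR adjusted p = 0.0352), a call lost without siCtrl replicate 1 (edgeR adjusted p = 0.265), siCtrl replicate 2 (0.0809) or siArid1a replicate 2 (0.119), with no filter on low counts (0.112), with legacy=FALSE (0.0584) and with limma-voom (0.0809).

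The genes that fell most with the Arid1a siRNAs were Kctd14 by 4.66-fold (log2 -2.22 ± 0.27), the trypsinogen gene Prss3 by 4.57-fold (log2 -2.19 ± 0.19), the FGF receptor gene Fgfr2 by 4.25-fold (log2 -2.09 ± 0.08), and Fam151a by 3.76-fold (log2 -1.91 ± 0.13). Next came the cyclin E1 gene Ccne1 by 3.28-fold (log2 -1.72 ± 0.10), the Mediator subunit gene Med28 by 3.24-fold (log2 -1.70 ± 0.10), the BMP antagonist gene Nbl1 by 3.17-fold and the tight junction gene Cldn1 by 3.16-fold. Prss3 belongs to a family of near-identical trypsinogens, and its value is uncertain. The 3′ UTR of Nbl1 holds 1 copy of a 7-base word that was more frequent among lowered genes. Of the S-phase and E2F genes, 2 of 33 rose, 18 fell and 13 did not pass. 4 higher and 20 lower passed when adjusted over the list alone (camera adjusted p = 8.22e-05, adjusted p = 0.728 with an estimated correlation). Rrm2 and E2f2 fell 1.52-fold and 1.71-fold. For cholesterol biosynthesis and SREBP2 targets, 0 of 24 rose, 13 fell and 11 did not pass. 0 higher and 13 lower passed when adjusted over the list alone (camera adjusted p = 4.68e-05, adjusted p = 0.728 with an estimated correlation), with Cyp51, Sc4mol and Insig1 down 1.70-fold, 1.67-fold and 1.39-fold. Among glycolysis and hypoxia genes, 4 of 30 rose, 15 fell and 11 did not pass. 4 higher and 17 lower passed when adjusted over the list alone (camera adjusted p = 0.0179, adjusted p = 0.728 with an estimated correlation). Its members Pkm2, Car9 and Ndrg1 fell 2.28-fold, 2.39-fold and 1.72-fold, and camera no longer called the list without siCtrl replicate 2 (adjusted p = 0.393) or siArid1a replicate 1 (adjusted p = 0.0674), or with the within-group component as a covariate (adjusted p = 0.112). Ptf1a fell 1.38-fold (log2 -0.47 ± 0.07) and Nfatc1, which encodes a calcineurin-regulated factor, fell 1.40-fold (log2 -0.48 ± 0.10). Cpa1 (log2 -0.27 ± 0.08), Nr5a2 (log2 -0.36 ± 0.11) and Bhlha15 (log2 -0.44 ± 0.15) were also called lower. Without siCtrl replicate 2 these 3 stood at log2 -0.24, -0.20 and -0.17 with edgeR adjusted p = 0.0662, 0.222 and 0.436, while Bhlha15 stood at -0.68 without siCtrl replicate 1. All 3 were lost without siArid1a replicate 1 (edgeR adjusted p = 0.0596, 0.0584 and 0.133). Nr5a2 was also lost without siArid1a replicate 3 (edgeR adjusted p = 0.0693), and Bhlha15 without siArid1a replicate 2 (0.0826), siArid1a replicate 3 (0.0605) or siArid1a_EGF replicate 3 (0.0640). Cpa1 and Bhlha15 were lost with only the groups compared (edgeR adjusted p = 0.0729 and 0.0559), and Nr5a2 and Bhlha15 with no filter on low counts (0.0508 and 0.0507). Bhlha15 was further lost with upper-quartile factors (edgeR adjusted p = 0.0637) and with limma-voom (adjusted p = 0.0720). Log2 changes of -0.23 ± 0.14 for Sox9, -0.35 ± 0.18 for Egfr, -0.47 ± 0.25 for Krt19 and 0.19 ± 0.09 for Dusp6 did not pass the test. Without siCtrl replicate 1, Sox9 and Egfr were called (log2 -0.51 and -0.58, edgeR adjusted p = 0.00145 and 0.0466), and Dusp6 was called without siCtrl replicate 2 (log2 0.31, edgeR adjusted p = 0.0401) and with upper-quartile factors (edgeR adjusted p = 0.0405).

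The quasi-likelihood test of edgeR called 5190 genes for the Arid1a siRNAs without EGF, 2505 higher and 2685 lower, 629 of them by more than 2-fold. Upper-quartile factors in place of TMM gave 3129 higher and 2025 lower, so the share called higher went from 48.3% to 60.7% with the scaling. Without siCtrl replicate 1, camera also called the enzymes (higher, adjusted p = 0.0227), the YAP targets (lower, 0.0484) and the fatty acid synthesis genes (lower, 0.0473).

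With EGF (n = 3 against n = 3), the interferon response genes were again higher with the Arid1a siRNAs: 30 of 36 rose, 0 fell and 6 did not pass. 30 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 7.84e-21, adjusted p = 0.101 with an estimated correlation), with a median log2 change of 1.07. Irf7, Igtp and Stat2 rose 3.84-fold (log2 1.94 ± 0.11), 2.55-fold (log2 1.35 ± 0.10) and 1.97-fold (log2 0.98 ± 0.06), and Ifit1 rose 4.49-fold (log2 2.17 ± 0.20). Of the 7 immune and endothelial markers 4 rose and 0 fell here (5 and 0 adjusted over the list alone), with a mean log2 change of 0.30 and a 95% interval from 0.147 to 0.455 (camera adjusted p = 0.618). P2rx6 rose 8.04-fold (log2 3.01 ± 0.17), Cel 5.66-fold (log2 2.50 ± 0.20), the secreted matrix protein gene Spon2 4.90-fold (log2 2.29 ± 0.10), Stac 4.47-fold, the receptor-modifying protein gene Ramp1 4.45-fold and Creb3l3 3.85-fold. The 3′ UTR of Ramp1 holds 1 copy of the word that Nbl1 holds. ERK target genes were lower than with control siRNA and EGF. Spry1, Dusp6 and Phlda1 fell 1.85-fold (log2 -0.89 ± 0.08), 1.67-fold (log2 -0.74 ± 0.07) and 1.58-fold (log2 -0.66 ± 0.05), and in the list of ERK feedback and ETS target genes, 3 of 26 rose, 13 fell and 10 did not pass. 3 higher and 13 lower passed when adjusted over the list alone (camera adjusted p = 0.00203, adjusted p = 0.509 with an estimated correlation). Sox9 and Bhlha15 fell 1.83-fold (log2 -0.87 ± 0.12) and 2.03-fold (log2 -1.02 ± 0.13), and Nr5a2 fell 1.45-fold (log2 -0.54 ± 0.10).

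The genes that fell most in this comparison were Wipi1 and Atg5, both genes of autophagy, by 4.52-fold (log2 -2.18 ± 0.12) and 3.42-fold (log2 -1.77 ± 0.08), the latter with 1 copy in its 3′ UTR of the word that Nbl1 holds, Prss3 by 3.76-fold, Kctd14 by 3.65-fold, and Med28, Cldn1 and Trib2 by 3.23-fold, 3.20-fold and 3.10-fold. Of the S-phase and E2F genes, 5 of 33 rose, 17 fell and 11 did not pass. 5 higher and 17 lower passed when adjusted over the list alone (camera adjusted p = 0.00227, adjusted p = 0.648 with an estimated correlation), with Ccne1 down 2.54-fold. For cholesterol biosynthesis and SREBP2 targets, 1 of 24 rose, 13 fell and 10 did not pass. 1 higher and 13 lower passed when adjusted over the list alone (camera adjusted p = 0.000196, adjusted p = 0.648 with an estimated correlation), with Mvk, Cyp51 and Sc4mol down 1.86-fold, 1.70-fold and 1.65-fold. For amino acid response and ATF4 genes, 14 of 29 rose, 3 fell and 12 did not pass. 14 higher and 3 lower passed when adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.648 with an estimated correlation): Nupr1 and Pck2 rose 1.89-fold and 1.79-fold. Among acinar digestive enzymes and secretory products, 12 of 28 rose, 4 fell and 12 did not pass. 12 higher and 5 lower passed when adjusted over the list alone (camera adjusted p = 0.0269, adjusted p = 0.814 with an estimated correlation): Gatm, an enzyme of creatine synthesis, rose 1.98-fold. For G2/M genes, 14 of 32 rose, 1 fell and 17 did not pass. 15 higher and 1 lower passed when adjusted over the list alone (camera adjusted p = 0.0316, adjusted p = 0.648 with an estimated correlation), with Kif20a and Cdc20 up 1.49-fold and 1.41-fold. Ptf1a (log2 -0.23 ± 0.07) and Nfatc1 (log2 -0.30 ± 0.09) were called lower. The call of Ptf1a was lost without siArid1a_EGF replicate 3 (edgeR adjusted p = 0.0560), and that of Nfatc1 without siCtrl_EGF replicate 1 (0.0513) or siCtrl_EGF replicate 3 (0.0734) and on FPKM with no filter (limma adjusted p = 0.0604). Cpa1 at log2 -0.17 ± 0.07 (edgeR adjusted p = 0.0507), Egfr at -0.31 ± 0.16 and Krt19 at 0.44 ± 0.26 did not pass. Cpa1 was called lower with no filter (edgeR adjusted p = 0.0146), RLE factors (0.0436), the replicate number as a block (0.0407, or 7.81e-08 with only the groups compared), only the groups compared without the block (0.00518), DESeq2 (0.0456), and without siArid1a replicate 1 (0.0338) or siArid1a replicate 3 (0.00577). The block with only the groups compared called Egfr lower as well (log2 -0.31, edgeR adjusted p = 9.22e-11). That fit has 2 residual degrees of freedom and was added after the data were seen, so its very small p-values for Cpa1 and Egfr are uncertain. Egfr was called neither with the block over all libraries nor with only the groups compared without the block.

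For the Arid1a siRNAs with EGF, edgeR called 6261 genes (3164 higher, 3097 lower), 761 of them by more than 2-fold. With upper-quartile factors the split was 3661 and 2613. The enzyme and G2/M lists were lost by camera without siCtrl_EGF replicate 1 (adjusted p = 0.0650 for both), siCtrl_EGF replicate 3 (0.0590 and 0.0592) or siArid1a_EGF replicate 2 (0.0723 and 0.0660).

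EGF was then compared with its vehicle in cells with Arid1a siRNAs (n = 3 against n = 3). The orphan receptor gene Gprc5a rose 8.84-fold (log2 3.14 ± 0.10), against 8.41-fold with control siRNA, with no difference called between them (edgeR adjusted p = 0.960 for the interaction). Etv4, Spry4 and the ERK phosphatase gene Dusp5 rose 7.02-fold (log2 2.81 ± 0.11), 6.01-fold (log2 2.59 ± 0.14) and 5.96-fold (log2 2.58 ± 0.13), and Dusp6 rose 4.43-fold (log2 2.15 ± 0.08). Samd5, the chemokine receptor gene Cxcr7, Has2 and Col15a1 rose 7.17-fold, 5.53-fold, 5.12-fold and 4.94-fold. Adra2a fell 3.18-fold (log2 -1.67 ± 0.11), Synpo2 3.05-fold (log2 -1.61 ± 0.14) and Pcdh8 2.60-fold (log2 -1.38 ± 0.09), followed by Cdc42ep3, Grhl3, Fam13a, Gpr37 and Cyp4v3 at 2.55-fold, 2.48-fold, 2.39-fold, 2.37-fold and 2.30-fold. Of the ERK feedback and ETS target genes, 15 of 26 rose, 0 fell and 11 did not pass. 17 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 1.27e-37, adjusted p = 0.00138 with an estimated correlation). Of the immediate early and AP-1 genes, 14 of 28 rose, 1 fell and 13 did not pass. 19 higher and 1 lower passed when adjusted over the list alone (camera adjusted p = 5.63e-09, adjusted p = 0.00450 with an estimated correlation). For amino acid response and ATF4 genes, 21 of 29 rose, 0 fell and 8 did not pass. 24 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 1.72e-16, adjusted p = 0.0213 with an estimated correlation), with Slc7a5, Mthfd2 and Psat1 up 1.61-fold, 1.58-fold and 1.52-fold. Cpa1 fell 1.31-fold (log2 -0.39 ± 0.07), Nfatc1 rose 1.33-fold (log2 0.41 ± 0.09), and Ptf1a had a log2 change of -0.01 ± 0.07. Egfr (log2 0.65 ± 0.16), Bhlha15 (log2 0.57 ± 0.14) and Sox9 (log2 0.39 ± 0.12) were called higher. Egfr was lost without siArid1a_EGF replicate 3 (edgeR adjusted p = 0.0568) and with no filter (0.0652), and Bhlha15 without siArid1a replicate 1 (0.0535) or siArid1a_EGF replicate 1 (0.0517). Sox9 was lost in edgeR with no filter (adjusted p = 0.0658) and without each of 5 libraries: siArid1a replicate 1 (0.130) or 2 (0.105), or siArid1a_EGF replicate 1 (0.0656), 2 (0.0753) or 3 (0.115). Nr5a2 and Krt19 did not pass (edgeR adjusted p = 0.0955 and 0.998).

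The other lists called in cells with Arid1a siRNAs went as follows. For cholesterol biosynthesis and SREBP2 targets, 16 of 24 rose, 0 fell and 8 did not pass. 18 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 9.81e-09, adjusted p = 0.150 with an estimated correlation), with Cyp51 and Insig1 up 1.33-fold and 1.29-fold. Among integrins, matrix and protease genes, 11 of 25 rose, 3 fell and 11 did not pass. 14 higher and 3 lower passed when adjusted over the list alone (camera adjusted p = 0.000264, adjusted p = 0.108 with an estimated correlation), with Plaur and Timp3 up 7.25-fold and 2.08-fold. Among mesenchymal and EMT genes, 8 of 21 rose, 0 fell and 13 did not pass. 8 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 0.000890, adjusted p = 0.0883 with an estimated correlation), with Tgfbi and Tgfb1 up 2.63-fold and 1.96-fold. For fatty acid synthesis and SREBP1 targets, 9 of 19 rose, 1 fell and 9 did not pass. 11 higher and 1 lower passed when adjusted over the list alone (camera adjusted p = 0.0124, adjusted p = 0.399 with an estimated correlation), with the elongase gene Elovl6 up 1.65-fold. For unfolded protein response genes, 10 of 23 rose, 2 fell and 11 did not pass. 12 higher and 2 lower passed when adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.221 with an estimated correlation), with Hyou1 and Xbp1 up 1.33-fold and 1.25-fold. Of the YAP and TEAD target genes, 5 of 19 rose, 0 fell and 14 did not pass. 6 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.221 with an estimated correlation), with Dlc1 and Axl up 2.02-fold and 1.64-fold. In the list of NF-kB and inflammatory genes, 7 of 15 rose, 1 fell and 7 did not pass. 7 higher and 1 lower passed when adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.150 with an estimated correlation), with the receptor antagonist gene Il1rn up 8.64-fold from 0.362 ± 0.155 CPM. For TGF-beta and BMP response genes, 7 of 19 rose, 2 fell and 10 did not pass. 7 higher and 2 lower passed when adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.108 with an estimated correlation), with Tgif1 up 1.83-fold. For Wnt pathway target genes, 2 of 12 rose, 0 fell and 10 did not pass. 2 higher and 0 lower passed when adjusted over the list alone (camera adjusted p = 0.0304, adjusted p = 0.221 with an estimated correlation), with Apcdd1 and Lgr5, which both respond to Wnt signals, up 2.88-fold and 1.83-fold. Of the EGF receptor family, ligands and regulators, 5 of 18 rose, 1 fell and 12 did not pass. 5 higher and 1 lower passed when adjusted over the list alone (camera adjusted p = 0.0304, adjusted p = 0.399 with an estimated correlation), with the feedback inhibitor gene Errfi1 and the ligand gene Hbegf up 2.09-fold and 1.74-fold. Other lists were lower. Of the G2/M genes, 0 of 32 rose, 18 fell and 14 did not pass. 0 higher and 22 lower passed when adjusted over the list alone (camera adjusted p = 2.76e-07, adjusted p = 0.0883 with an estimated correlation). Of the interferon response genes, 1 of 36 rose, 18 fell and 17 did not pass. 1 higher and 23 lower passed when adjusted over the list alone (camera adjusted p = 3.71e-07, adjusted p = 0.150 with an estimated correlation). Among acinar digestive enzymes and secretory products, 1 of 28 rose, 10 fell and 17 did not pass. 1 higher and 10 lower passed when adjusted over the list alone (camera adjusted p = 0.000890, adjusted p = 0.399 with an estimated correlation). Among S-phase and E2F genes, 1 of 33 rose, 6 fell and 26 did not pass. 1 higher and 6 lower passed when adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.456 with an estimated correlation). Nusap1, Irf7, Reg1 and E2f2 fell 1.5-fold, 1.68-fold, 1.49-fold and 1.34-fold. Prss2, a trypsinogen gene whose reads can be shared with its paralogs, rose 1.53-fold in the enzyme list.

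For EGF with Arid1a siRNAs, edgeR called 3119 genes (1734 higher, 1385 lower), 287 of them by more than 2-fold. Upper-quartile factors turned the majority, with 1509 higher and 1683 lower. Without siArid1a replicate 3, camera no longer called the YAP (adjusted p = 0.0759), Wnt (0.0801), S-phase (0.0863) or EGF receptor family (0.180) lists, the last of which was also lost without siArid1a_EGF replicate 3 (0.0887). The glycolysis and hypoxia list was called higher without siArid1a replicate 3 (0.0106). With the within-group component as a covariate, camera no longer called the Wnt (adjusted p = 0.0994) and NF-kB (0.0940) lists.

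Whether the EGF response itself differs with the Arid1a siRNAs was tested as an interaction over all 11 libraries, with negative values for a smaller rise or a larger fall. ERK target genes responded less. Spry1 rose 8.57-fold with EGF after control siRNA and 3.39-fold after Arid1a siRNAs (interaction log2 -1.34 ± 0.14, edgeR adjusted p = 0.000697), and Dusp6 8.48-fold and 4.43-fold (interaction log2 -0.94 ± 0.11, edgeR adjusted p = 0.00149). Spry2 rose 4.78-fold and 2.96-fold (interaction log2 -0.69 ± 0.08). In the list of ERK feedback and ETS target genes, 7 of 26 had a lower response, 0 a higher one and 19 did not pass, with 8 lower and 0 higher when adjusted over the list alone (camera adjusted p = 7.67e-19, adjusted p = 0.0182 with an estimated correlation), at a median of -0.41. Wipi1 rose 3.10-fold with EGF after control siRNA and had a change of 1.01-fold after Arid1a siRNAs, which did not pass (interaction log2 -1.62 ± 0.19, edgeR adjusted p = 0.00128). The falls of Pcdh8, Olfml2b and Apol7a were smaller with Arid1a siRNAs (interactions log2 1.39 ± 0.13, log2 1.09 ± 0.13 and log2 1.09 ± 0.18). Among progenitor and Notch pathway genes, 2 of 25 had a higher value, 1 a lower one and 22 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.0391, adjusted p = 0.526 with an estimated correlation). Its members Dll1 and the Notch feedback gene Nrarp had interactions of 0.64 ± 0.08 and 0.85 ± 0.12, and Klf4 of -1.02 ± 0.15. For the acinar and ductal genes Sox9, Bhlha15, Ptf1a, Nr5a2, Cpa1 and Krt19 and for Egfr and Nfatc1 no difference was called (lowest edgeR adjusted p = 0.154, for Sox9). With the within-group component as a covariate, edgeR called Sox9, Bhlha15 and Ptf1a (adjusted p = 0.0353, 0.00246 and 0.00938), with Ptf1a at log2 0.24. That component was drawn from the same libraries and removes their spread within groups. Smaller p-values are thus in part built in, and these calls are no separate support. The value for Sox9 rested on the control libraries: its interaction of -0.64 ± 0.18 became -0.97 without siCtrl replicate 2 (edgeR adjusted p = 0.00308) and -0.36 without siCtrl replicate 1 (edgeR adjusted p = 0.300), and DESeq2 called it (adjusted p = 0.0430). Bhlha15, at -0.58 ± 0.20, was called without siCtrl replicate 2 (-0.85, edgeR adjusted p = 0.0468).

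The interaction was called for 126 genes by edgeR (75 higher, 51 lower), with a split of 53 and 52 with upper-quartile factors and of 58 and 53 with RLE factors. Of the 126, 125 were called for EGF with control siRNA: 51 rose there and had a lower value with Arid1a siRNAs, 73 fell there and had a higher value, and 1 had a larger rise. Among these, 7 were called in opposite directions: 3 rose with control siRNA and fell with Arid1a siRNAs, and 4 fell with control siRNA and rose with Arid1a siRNAs. The interaction subtracts the EGF change with control siRNA, so chance values of those libraries favour opposite signs of that change and the interaction. The number of calls went down to 55 without siCtrl_EGF replicate 1, 63 without siCtrl replicate 1 or without siArid1a_EGF replicate 1, 65 without siCtrl_EGF replicate 3, 76 without siArid1a replicate 1, 78 without siArid1a_EGF replicate 3 and 81 without siArid1a replicate 2. The progenitor and Notch list was lost by camera without siCtrl replicate 2 (adjusted p = 0.298), siCtrl_EGF replicate 2 (0.0857), siCtrl_EGF replicate 3 (0.0564), siArid1a replicate 1 (0.0756) or siArid1a_EGF replicate 1 (0.0995). Other lists were called higher for the interaction by camera when 1 library was left out: the enzymes without siCtrl replicate 2 (adjusted p = 6.80e-05), siCtrl_EGF replicate 2 (0.00621) or siArid1a replicate 3 (0.00593). The G2/M genes were so called by camera without siCtrl replicate 2 (0.0159), siCtrl_EGF replicate 2 (0.0180) or siArid1a replicate 1 (0.0379), and the glycolysis genes without siCtrl replicate 1 (0.000814), siCtrl_EGF replicate 3 (0.0302) or siArid1a replicate 3 (0.0115). Camera also called the amino acid response genes without siArid1a replicate 3 (0.0115) and the fatty acid synthesis genes without siCtrl replicate 1 (0.00229).

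**Figure D3:**
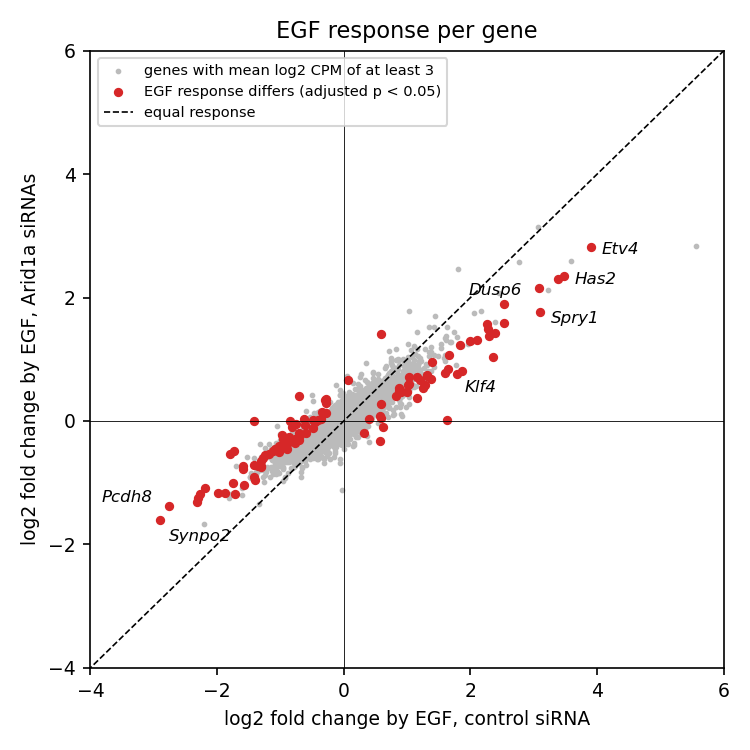
Log2 fold change by EGF with control siRNA (x axis) against that with Arid1a siRNAs (y axis) for each gene with a mean log2 CPM of at least 3, with genes whose response differed by edgeR (adjusted p under 0.05) in red and the dashed line at equal response. Dusp6 lies below the line on the side of rises (3.08 and 2.15), and Pcdh8 above it on the side of falls (-2.76 and -1.38).

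Across genes, which are not independent replicates, the EGF responses with control and with Arid1a siRNAs correlated at Pearson 0.81 and Spearman 0.79 over 13343 genes, with no library in common. Both comparisons called 1480 genes higher (291 for independent lists) and 1182 lower (260), and 8 in opposite directions. Among the 2670 genes called in both, the response with Arid1a siRNAs was smaller for 84.1%, with a median ratio of 0.748. In 20 simulations with equal effects in both arms and the group sizes of the data, that share was 54.1% (52.7 to 56.4%), the median ratio 0.975 (0.961 to 0.982), and at most 4 genes were called for the interaction. The simulations draw the spread of each gene separately, so their ranges leave out spread shared across genes. Responses to the Arid1a siRNAs without and with EGF correlated at 0.80 (Spearman 0.81), with 2079 genes higher in both (594 for independent lists), 2120 lower (623) and 36 opposite.

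EGF and the Arid1a siRNAs were both compared with the same 2 control libraries, so their changes share the chance values of those libraries. The correlation across genes was 0.033 (Spearman -0.05) against 0.57 in 50 simulations of unchanged groups, and the covariance was 0.00850 against a simulated 0.0172 (SD 0.000523), a difference of -0.00869. Both raised 390 genes (420 for independent lists) and lowered 570 (504), and 1240 went in opposite directions (921). The same sign was found in 46.8% of genes, against 69.8% in the simulations. Simulated groups hold no true changes, so their correlations and share of same signs reflect shared chance alone and are not directly comparable. The covariance is the closer comparison. Unchanged groups gave on average 0.16 genes called in both. No split of the 2 control libraries leaves 2 for each comparison. With EGF measured in the cells with Arid1a siRNAs instead, which shares that group with the opposite sign, the correlation was -0.14 against -0.47 in 50 simulations of unchanged groups, and the covariance was -0.0272 against a simulated -0.0134 (SD 0.000521).

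Camera called 42 of 135 list tests, of which 6 hold with an estimated correlation: the ERK and immediate early lists for EGF in both arms, the amino acid response list for EGF with Arid1a siRNAs, and the ERK list for the interaction. List median, mean and camera direction had the same sign in each of the 42, and differed in 23 of the other 93. Not called in any of the 5 comparisons were 7 lists. Their calls with EGF after control siRNA and with Arid1a siRNAs without EGF were counted. Among 17 tested acinar transcription factors and receptors, 6 rose and 5 fell with EGF and 5 rose and 6 fell with Arid1a siRNAs (lowest camera adjusted p = 0.701), with median and camera direction of opposite sign in both. Among 15 NFAT genes and calcineurin regulators, 0 rose and 3 fell with EGF, and 2 rose and 5 fell with Arid1a siRNAs (lowest camera adjusted p = 0.297), but camera called them without siCtrl replicate 1 with Arid1a siRNAs (lower, adjusted p = 0.0499) and for the interaction (higher, adjusted p = 0.0256). Among 29 SWI/SNF subunits, 3 rose and 8 fell with EGF, and 3 rose and 9 fell with Arid1a siRNAs (lowest camera adjusted p = 0.375). Among 25 p53 target genes, 9 rose and 5 fell with EGF, and 6 rose and 4 fell with Arid1a siRNAs (lowest camera adjusted p = 0.131). Markers of other cell types were counted likewise. Among 12 tested of 25 listed endocrine islet markers, 4 rose and 3 fell with EGF, and 3 rose and 4 fell with Arid1a siRNAs (lowest camera adjusted p = 0.520). Among 14 of 21 fibroblast and stellate markers, 3 rose and 2 fell with EGF, and 5 rose and 2 fell with Arid1a siRNAs (lowest camera adjusted p = 0.433). Among 7 of 22 immune and endothelial markers, 3 rose and 2 fell with EGF, and 3 rose and 1 fell with Arid1a siRNAs (lowest camera adjusted p = 0.424).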

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

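The tests of the word in further genes, of immune cell RNA, of siRNA sensing and of a proportional response were chosen only after the result was seen.

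A test of the difference between the EGF responses with Arid1a and with control siRNAs (the edgeR interaction term) called 126 genes, and camera called 2 lists. The median log2 interaction was -0.41 for the ERK list and 0.10 for the progenitor and Notch list. Smaller rises, or a rise lost, gave log2 interactions of -1.62 for Wipi1, -1.34 for Spry1, -1.31 for Daf2, -1.12 for Has2, -1.09 for Etv4, -1.08 for Col15a1, -1.06 for Hbegf, -1.02 for Klf4, -0.94 for Dusp6, -0.69 for Spry2 and -0.69 for Phlda1. Positive log2 interactions were 1.42 for Nptxr, 1.39 for Pcdh8, 1.29 for Synpo2, 1.26 for Adrb1, 1.25 for Omp, 1.11 for Klf2, 1.09 for Apol7a, 1.09 for Olfml2b, 0.85 for Nrarp and 0.64 for Dll1. Without siCtrl replicate 1 the edgeR calls of Col15a1, Etv4, Has2 and Nptxr were lost (adjusted p = 0.0910, 0.0717, 0.0708 and 0.0752), and that of Nptxr was also lost without siCtrl_EGF replicate 1 (0.0586). Synpo2 was lost in edgeR without siCtrl_EGF replicate 3 (adjusted p = 0.0558) or siArid1a_EGF replicate 1 (0.0560). Omp was lost in edgeR without siCtrl replicate 1 (adjusted p = 0.0671), siCtrl_EGF replicate 1 (0.0586), siArid1a replicate 1 (0.0503) or siArid1a_EGF replicate 1 (0.0530). Klf2 was lost in edgeR without siCtrl replicate 1 (adjusted p = 0.224), siCtrl_EGF replicate 1 (0.116) or 3 (0.121), siArid1a replicate 1 (0.132) or 2 (0.138), or siArid1a_EGF replicate 1 (0.138), 2 (0.0522) or 3 (0.125). It was also lost with RLE factors (edgeR adjusted p = 0.0544), upper-quartile factors (edgeR adjusted p = 0.0551) and limma-voom (adjusted p = 0.0544). With the progenitor and Notch list, the camera call was lost without siCtrl replicate 2 (adjusted p = 0.298), siCtrl_EGF replicate 2 (0.0857) or 3 (0.0564), siArid1a replicate 1 (0.0756) or siArid1a_EGF replicate 1 (0.0995).

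For the smaller EGF response of ERK target genes, the list kept a negative median interaction, of -0.32 at the nearest to 0, and its camera call without either siCtrl library, which argues against 1 control library as the whole source. A response of all EGF-responsive genes smaller in 1 proportion would give the amino acid response list a mean interaction of -0.0967, whereas it was 0.12 with a 95% interval from 0.0279 to 0.216, which argues against 1 proportion for all of them. The intervals of the other 10 lists that EGF moved with control siRNA include their proportional values, 3 of them without 0, with no adjustment over lists. The median ratio over the 2670 genes called in both arms was 0.748 (0.975 in simulations of equal effects). Smaller responses were thus seen outside the ERK list. The simulations draw the spread of each gene separately and leave out spread shared across genes, such as the within-group component. They cannot tell whether an error shared by the control libraries gave the ratio, which was not computed without either of them. Whether the 10 lists share the proportion of the ERK list stays open, as 7 of the intervals hold both that value and 0. With the within-group component as a covariate the upper limit of the ERK list's mean interaction was -0.31, but that component is centred within each group and cannot move the mean, so structure within groups and an effect of the siRNAs, by lower Arid1a or otherwise, cannot be told apart by it.

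For interferon response genes, higher with the Arid1a siRNAs, other scalings left a median log2 change of at least 1.03, which argues against scaling. The summed level of 6 immune cell markers had its highest group mean, 6.84 CPM, with Arid1a siRNAs without EGF, which fits RNA from immune cells as the test was written. Of the 682 reads of these markers 611 were of Laptm5. The highest group mean of the summed other 5 markers was 0.626 CPM, which argues against immune cells that carry those markers. In single libraries Fcer1g alone reached 0.746 CPM. Sensing of the siRNA molecules and loss of Arid1a cannot be told apart, since the same groups differ in both (median log2 change 1.02 without EGF). Both may be candidate sources of the change. No concentration is recorded for the control siRNA, so an equal amount of siRNA in the groups cannot be assumed.

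For genes lowered with the Arid1a siRNAs, the 3′ UTR word GCCTCTA had a z of -11.5 over both siRNA comparisons, beyond the lowest of any word in 100 permutations (-4.68) and in the EGF responses (-4.66). Chosen from 5762 genes without EGF, the same word had a z of -7.40 in the other 5762 genes with EGF. It stood in 8.04% of 11524 genes, in 18.1% and 18.8% of those called more than 2-fold lower without and with EGF, and in 3.30% and 3.79% of those more than 2-fold higher. A seed match of 1 of the siRNAs, whose sequences are not given, may therefore account for part of the lower genes, by about -0.19 on the log2 scale per gene with the word. Most of the largest falls lack this exact word: of 10 such genes with a 3′ UTR, 2 (Atg5 and Nbl1) hold it, and of 11 largest rises 1 (Ramp1) holds it. Overlapping words also had a low z over both siRNA comparisons, such as AGCCTCT (-7.66) and TGCCTCT (-6.16). These were not looked up in the named genes, so other seed matches there stay open.

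For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05, with 1 split, the real one, calling as many genes in each. In fits of only the libraries compared, over 12880 and 12896 genes, the real split called 6662 genes for Arid1a siRNAs with EGF and 2981 for EGF with Arid1a siRNAs. The highest of the other splits called 0 by edgeR, where 22 to 966 genes had an unadjusted p under 0.05. Each other split mixes both groups, so differences between them enter its spread. Its 0 calls are therefore no measure of chance. For Arid1a siRNAs with EGF, where replicate numbers may pair the libraries, the real split parts 3 same-number pairs, as do 3 of the other splits (22 to 31 genes with an unadjusted p under 0.05). The remaining 6 part 1 such pair (35 to 358 genes).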

How the results depend on the processing

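The within-group component as a covariate, upper-quartile factors for the lists, and the replicate block with only the groups compared, were chosen after seeing the data. Of 5505 alternative values for 245 results on named genes, which leave out Arid1a with the siRNAs, 5403 kept their direction and side of the threshold, 71 lost a call, 31 gained one and 0 reversed. Arid1a stayed lower in all alternatives run, from -1.46 to -1.01 without EGF and from -1.12 to -0.97 with EGF when 1 library was left out. Called genes then ranged from 3648 to 5039 for EGF with control siRNA, 3904 to 5279 and 5382 to 6549 for Arid1a siRNAs without and with EGF, 2217 to 3399 for EGF with Arid1a siRNAs, and 55 to 153 for the interaction, and list calls from 38 to 44. Without a siCtrl library, the lone control is assumed to vary like the other groups. In the same order, a minimum change of 1.5-fold gave 610.0, 490.0, 787, 195 and 3 genes, by its stricter construction, and an adjusted p under 0.01 gave 3084, 3362, 4525, 1731 and 36. The replicate number as a block gave 4063, 4408, 5866, 2616 and 56, of which the interaction count moved by more than 1.5 times. In the comparison of Arid1a siRNAs with EGF, where the numbers may pair the libraries, the block with only the 2 groups compared and 2 residual degrees of freedom called 8362 genes. There the block over all libraries gained only the call of Cpa1, and the block with only the groups compared gained those of Cpa1, Egfr and Arid2. Cpa1 was called with only the groups compared without the block too. Neither fit with the block changed another call of a named gene or list in this comparison. In the other comparisons pairing was not shown: their same-number pairs correlated at -0.38 to 0.32 in within-group deviations, and 3 of all 11 libraries correlated best with their own number. It was not excluded either where control siRNA without EGF takes part, as only 2 such pairs exist there. For control against Arid1a siRNAs without EGF both were positive (0.05 and 0.32). With the block, edgeR did not call Bhlha15 for Arid1a siRNAs without EGF (adjusted p = 0.0643), or Klf2, Omp and Synpo2 for the interaction (0.146, 0.0872 and 0.0599). Camera called the amino acid response and the glycolysis lists higher for the interaction (adjusted p = 0.0403 each). The covariate gave 5212 for EGF with Arid1a siRNAs and 801 for the interaction, because it removes spread within groups. It gained 11 calls of named genes and lost 0. As the component was drawn from the same libraries, calls gained with this covariate are no separate support. With it, camera also called the EGF receptor family for EGF with control siRNA (adjusted p = 0.0411), the YAP targets lower for Arid1a siRNAs with EGF (0.0311), and the enzymes (0.0227) and G2/M genes (0.00747) for the interaction. Of the 135 list tests 42 were called by camera, 6 with an estimated correlation, and by fry 69 one way and 120.0 in either direction, since fry does not compare a list with other genes. At a mean log2 CPM of at least 3, the correlations of the EGF and of the siRNA responses were 0.90 and 0.89. Over all genes tested, the correlation of the EGF response in cells with Arid1a siRNAs and the siRNA response without EGF was -0.14 (-0.47 in simulations of unchanged groups). Simulated groups hold no true changes, so these 2 correlations are not directly comparable. The covariance was -0.0272, more negative than the simulated -0.0134 (SD 0.000521). The cause was not tested where none is given. FPKM alternatives were not run for comparisons that need control siRNA without EGF, or for the interaction, as 3 columns cannot be matched to 2 libraries. On FPKM with a pseudocount of 1, log2 changes were smaller by over 1.5 times, with their calls kept, for P2rx6 and Ifit1 with Arid1a siRNAs and EGF, and for Synpo2, Spry4, Col15a1, Lgr5 and, with no filter, Il1rn for EGF with Arid1a siRNAs. Few reads leave genes near 1 CPM, such as Krt19 and Il1rn, uncertain. Small changes can be missed as well: 41.8% of simulated 1.5-fold interactions were recovered. At the same depths the share was 79.1% for Arid1a siRNAs with EGF, so depth alone does not set it.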

Other observations

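The test with the within-group component was chosen after the data were seen, and the values here are given without explanation.

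Libraries differed within groups along 1 component, with 31% of the within-group variance of log2 CPM. Its scores were 14.0 and -14.0 for siCtrl replicates 1 and 2, and -6.10, 11.3 and -5.19 for siCtrl_EGF replicates 1 to 3. They were -2.0, -10.1 and 12.1 for siArid1a, and -7.57, 14.3 and -6.78 for siArid1a_EGF. The first 3 principal components of all libraries held 50.7%, 25.4% and 6.38% of the variance. The summed level of the 6 immune cell markers was 4.26 ± 0.158 CPM (n = 2) with control siRNA, 2.58 ± 0.920 with control siRNA and EGF, 6.84 ± 1.31 with Arid1a siRNAs and 4.16 ± 0.499 with Arid1a siRNAs and EGF (SD, n = 3 each).

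The word most associated with higher values under the Arid1a siRNAs was AGACTAA (z 5.63, against a highest of 5.02 in the permutations). The longest Arid1a coding transcript, of 8187 bases, holds 1 copy of GCCTCTA where 0.50 are expected with equal shares of the 4 bases, and its 3′ UTR holds 0.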
